A study of Homo sapiens with 38 samples.

How the data were processed

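Expression was measured on 38 Affymetrix arrays of RNA from A549 cells, a human lung adenocarcinoma line with features of alveolar epithelium. Per the labels' protocols, the cells were transfected with a pool of siRNAs against ORMDL3 or served as controls, were silenced for 48 h, were kept without serum for 24 h and then received 1 ng/ml interleukin 1 beta (IL1B). The labels give no more than the word control for the other arm, so what those cells were transfected with is not given in the sources used here. Arrays were grouped by arm and by hours of IL1B (0, 2, 4, 8 and 10 h), with the group and the replicate number both read from the labels. The arrays at 0 h were untreated, and no later hour had an untreated array. Changes from 0 h, called IL1B effects here, may therefore include effects of the further hours in culture. The protocol also names collections at 6 and 24 h, which are not analysed here. Each group held 4 arrays, except control 8 h and knockdown 0 h with 3 each, so that 19 arrays stood in each arm. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

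The values were log2 expression levels per probe set, deposited by the authors, and the submitters' processing notes name Affymetrix Power Tools, RMA, limma 3.22.7 and the genome build hg19, without a role or an order for any of them. The table held 14488 probe sets for each of the 38 arrays and no missing value. How these probe sets were chosen is not given in the sources used here. The median of an array lay between 8.02 and 8.19, its minimum between 2.94 and 3.84 and its maximum between 13.8 and 14.0. No further normalization was applied. A gene was named only through the platform annotation, in which 12132 probe sets had 1 gene symbol, 628 had several and 1728 had none. Of the 12132 probe sets, 12121 were matched to current gene records by Entrez identifier, and the symbols stood for 11893 distinct genes, 209 of them with more than 1 probe set. Probe sets were tested singly, a gene named from a probe set with 1 symbol stands for that probe set, and no coordinates were used. Levels of different probe sets were not set against each other, except to choose 1 probe set per gene for the lists and to leave out dim ones. No detection values were used, and the number of arrays limits the precision.

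The tests were made with limma 3.58.1 in R 4.3.3. A linear model with 1 mean for each of the 10 groups was fitted to all 38 arrays, so that the groups shared 1 estimate of the spread, with empirical Bayes moderation, no variance trend and no robust option. Contrasts compared IL1B with 0 h at each hour and as the mean of 4 hours within each arm, knockdown with control at each of the 5 hours and as their mean, and the IL1B response of the knockdown arm with that of the control arm at each hour, as the mean of 4 hours and in a joint F test. The p-values were adjusted by the Benjamini-Hochberg method over all 14488 probe sets for each contrast, and a probe set is called when its adjusted p is under 0.05. Fold changes are log2 differences of group means, given ± the standard error of limma's model, and every adjusted p for a gene is limma's. ORMDL3 and the means of gene lists per array were also compared by exact two-sided permutation tests, or by permutation within hours with 100000 resamples where hours were pooled. With 3 or 4 arrays in a group, the smallest exact p at a single hour is 0.029. Comparisons of IL1B with 0 h share the 0 h arrays of their arm, and no overlap or correlation between them is given.

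The genes named were taken by a rule. It took ORMDL3 and its paralogs ORMDL1 and ORMDL2, and the 12 highest and 12 lowest knockdown means with 1 sign at all 5 hours. For each IL1B contrast in controls it took the 8 highest and 4 lowest genes, for knockdown at each hour the 3 highest and 3 lowest, and for the difference in response the 10 smallest joint p-values and the 2 highest and 2 lowest at each hour. It also took up to 4 members with the largest change per gene list and contrast, and a fixed set of inflammatory, sphingolipid and stress genes. Not every gene that the rule takes is printed. GSDMB, which the fixed set held, was not among the measured genes with 1 symbol.

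The gene lists, 25 in all, covered cytokines and chemokines, NF-kB subunits and feedback regulators, IL1 receptor and proximal signalling, immediate-early and MAP kinase feedback, adhesion, acute-phase and protease genes, prostaglandin and leukotriene genes, interferon-stimulated genes, MHC class I antigen presentation, sphingolipid de novo synthesis, sphingolipid turnover with complex sphingolipids and S1P receptors, the unfolded protein response, the ATF4 and amino acid response, cholesterol synthesis and uptake, fatty acid and glycerolipid synthesis, glycolysis, oxidative phosphorylation, mitosis, DNA replication, p53 targets, NRF2 targets, calcium stores, the 17q12-q21 neighbours of ORMDL3, and markers of lung epithelium, leukocytes, and fibroblasts and endothelium. Each was tested against all other probe sets with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists, for 3 contrasts: IL1B in controls, knockdown and the difference in response, each as the mean over hours. The test was repeated with an estimated correlation and with fry. Counts refer to measured members, which were only a part of some lists. Measured were 6 of 17 MHC class I genes, 9 of 21 lung epithelial, 4 of 13 leukocyte and 2 of 11 fibroblast and endothelial markers. Whether the choice of probe sets for the table favoured genes that change in these samples is not known, so the shares of members called may depend on it.

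The design, the rule for genes, the lists and most alternatives were set before the data were examined. These alternatives were the replicate number as a fixed or as a random block, a variance trend with robust moderation, array weights, the exclusion of probe sets below the median level, quantile normalization, subtraction of each array's median, averaging of probe sets per gene, a fit to only the arrays compared, the other 2 list tests, an exchange of the axes in the comparison of responses, and each array left out in turn. Chosen after seeing the data were 3 more: an array score as a covariate, the median level of 104 small nucleolar RNA probe sets as a covariate, and the exclusion of all arrays numbered 4. The array numbered 4 was highest on the first component described next in each of the 9 groups that have one, and the median correlation of same-numbered arrays was 0.32 for number 4 against 0.08 to 0.16 for the other numbers. The array score summarises the first component of the differences between arrays of 1 group, which held 21.9% of that variance, over 2806 probe sets with an unadjusted p above 0.2 both for the mean IL1B effect over the arms and for the mean knockdown effect.

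The labels number the replicates 1 to 4 in each group, except that control 8 h has no 4 and knockdown 0 h no 3, without saying what a number marks. The check correlated each array's deviations from its group mean with those of same-numbered arrays. Over 162 same-numbered pairs the median correlation was 0.18, with a range of -0.29 to 0.62, against -0.06 for differently numbered pairs. Every same-numbered pair lay above 0.1 in 8 of the 13 pairs of compared groups, namely control 0 h with control 2, 4 and 8 h, control 0 h with knockdown 0 h, and knockdown 0 h with each later knockdown group. The numbers were taken to pair samples in those comparisons only, by this limit of 0.1, although counts under the block had been seen in an earlier look at the data. The exact permutation tests at 0 h took no account of this pairing. Only 8 splits part every pair there, too few for a p under 0.05. Within groups, 54 pairs of arrays were compared, the SD of their differences was 0.171 to 0.304, and at most 3 values were identical in any pair, so no array was taken for a copy of another.

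The tests were tried on simulated data made with the real levels and spreads and with noise drawn independently for each probe set. In these data 200 of 14488 probe sets were changed, 50 at each of 4 sizes. At 1.2-fold, 1.5-fold, 2-fold and 4-fold, the model recovered 22%, 86%, 98% and 100% of them for knockdown at 2 h, with 6 calls among unchanged probe sets. For the knockdown mean of 5 hours it recovered 88%, 100%, 100% and 100%, with 14 such calls, and for the difference in response at 8 h it recovered 2%, 44%, 94% and 100%, with 3 such calls. Deviations that the probe sets of an array share were not simulated, so false calls in the real data may be more frequent.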

Results

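ORMDL3 encodes a membrane protein of the endoplasmic reticulum that restrains serine palmitoyltransferase, the enzyme that starts sphingolipid synthesis. The series compared A549 cells depleted of ORMDL3 with control cells before and during stimulation by the cytokine IL1B, which activates NF-kB. The 38 arrays formed 10 groups, with 4 arrays in each group except control 8 h and knockdown 0 h, which had 3. Log2 levels of all probe sets in the table were compared for the effect of IL1B in control cells, the effect of knockdown at each hour and the difference in IL1B response between the arms. All changes are given on the log2 scale.

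ORMDL3 was lower in every knockdown array than in any control array, at 5.00 to 5.57 against 6.78 to 7.77 over all hours. At 0 h its level was 5.38 ± 0.17 (SD, n = 3) in knockdown and 7.17 ± 0.19 (SD, n = 4) in controls. At 10 h it was 5.28 ± 0.05 (SD, n = 4) and 7.63 ± 0.11 (SD, n = 4). Knockdown left 28.9%, 24.3%, 31.3%, 23% and 19.6% of the control level at 0, 2, 4, 8 and 10 h, with an exact two-sided permutation p of 0.029 at each hour, the smallest possible. The knockdown levels lay below the lower quartile of every array, 6.525 to 6.701. Signal over background was not given, so these percentages compare array levels and may differ from the share of transcript left. Over the 5 hours the difference was -1.99 ± 0.05 (permutation p = 1e-05, the smallest that 100000 resamples can give), or 25.1% of control. It was the largest of all probe sets, and the next largest had a size of 0.88. The paralogs changed less: ORMDL1 fell by 0.17 ± 0.04 (limma adjusted p = 0.00274) and ORMDL2 fell by 0.09 ± 0.03 (adjusted p = 0.016). In control cells ORMDL3 rose after 10 h of IL1B by 0.45 ± 0.11 (adjusted p = 0.00109), and its change at 8 h was 0.37 ± 0.12 (adjusted p = 0.0118). The call at 8 h was lost without control 0 h replicate 4 (0.29, adjusted p = 0.064), without control 8 h replicate 1 (0.33, adjusted p = 0.0628) and with the small nucleolar RNA level as a covariate (0.36, adjusted p = 0.051). The call for ORMDL2 was lost without the arrays numbered 4 (-0.08, adjusted p = 0.0947).

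**Figure D1:**
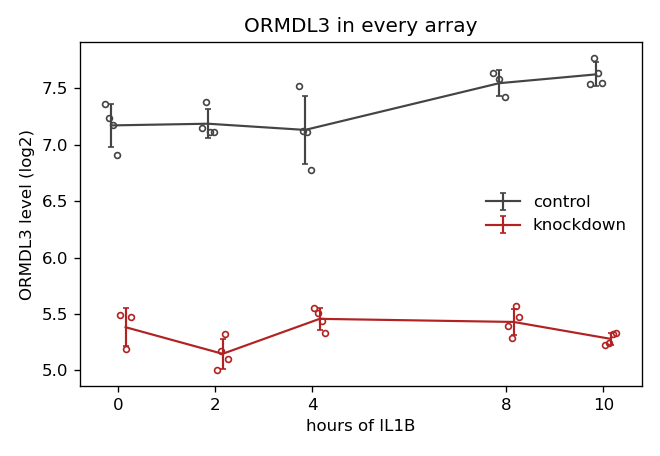
ORMDL3 level (log2) against hours of IL1B. Open circles are single arrays, lines join group means and bars show the SD, with controls in dark grey and knockdown in red; the knockdown arrays lie at 5.00 to 5.57, below all control arrays at 6.78 to 7.77.

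The first comparison asked which genes IL1B changed in control cells. Each hour was compared with 0 h, and without untreated arrays at the later hours, effects of time in culture could not be told apart from those of IL1B. The strongest rises at 2 h were those of CCL20, a chemokine for dendritic cells and lymphocytes (7.44 ± 0.15), the cytokine IL1A (6.56 ± 0.17), the adhesion molecule ICAM1 (6.30 ± 0.11) and the chemokine CCL5 (6.23 ± 0.15). IL6, the endothelial adhesion molecule SELE and the vesicle protein STX11 followed with 4.99 ± 0.12, 4.93 ± 0.15 and 4.84 ± 0.12, and the IL1B gene itself rose by 4.67 ± 0.15. CCL20 went from a level of 5.09 ± 0.29 (SD, n = 4) at 0 h to 12.53 ± 0.10 (SD, n = 4) at 2 h and 10.89 ± 0.23 (SD, n = 4) at 10 h. Genes that fell by 2 h included CCN1 (-2.55 ± 0.14) and CCN2 (-1.81 ± 0.11), matricellular proteins, as well as PDK4 (-2.40 ± 0.15), a kinase that inhibits pyruvate dehydrogenase, and RNF43 (-1.85 ± 0.13), a ubiquitin ligase that limits Wnt signalling. At 4 h, TNFAIP6 (6.01 ± 0.16), a hyaluronan-binding protein, and OLR1 (5.85 ± 0.17), a scavenger receptor, joined the strongest rises, while SLITRK6 (-2.78 ± 0.23), RNF43 (-2.53 ± 0.13), PRAG1 (-2.27 ± 0.14) and LBH (-2.19 ± 0.11) fell most.

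At the later hours CCL5 rose most, by 6.60 ± 0.16 at 8 h and 6.63 ± 0.15 at 10 h, ahead of CCL20 with 5.72 ± 0.16 and 5.79 ± 0.15. The protease inhibitor PI3 (4.86 ± 0.24), the costimulatory receptor TNFRSF9 (4.58 ± 0.12) and the acute-phase protein SERPINA3 (4.39 ± 0.18) were among the strongest rises at 8 h. NRG4 (-2.26 ± 0.18), PCDH9 (-2.22 ± 0.13), DEPTOR (-2.10 ± 0.13), an inhibitor of mTOR, and NCALD (-2.10 ± 0.22) fell most at 8 h, and RAP1GAP (-2.17 ± 0.11) fell most at 10 h. As the mean of 4 hours, CXCL8 rose by 3.16 ± 0.08, CCL2 by 2.68 ± 0.06, CSF3 by 4.30 ± 0.13, NFKBIA by 1.01 ± 0.05 and PTGS2 by 0.96 ± 0.06. The chaperone HSPA5 (0.00 ± 0.05) and the serine palmitoyltransferase subunit SPTLC2 (-0.12 ± 0.06) did not pass the test. In all, 2904 probe sets were called at 2 h (1488 up and 1416 down), 5484 at 4 h (2459 and 3025), 4969 at 8 h (2371 and 2598) and 5030 at 10 h (2568 and 2462). Over the mean of 4 hours 5688 were called, 2623 up and 3065 down. Fewer than this were called when probe sets below the median level were left out, 3304 for the mean.

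**Figure D2:**
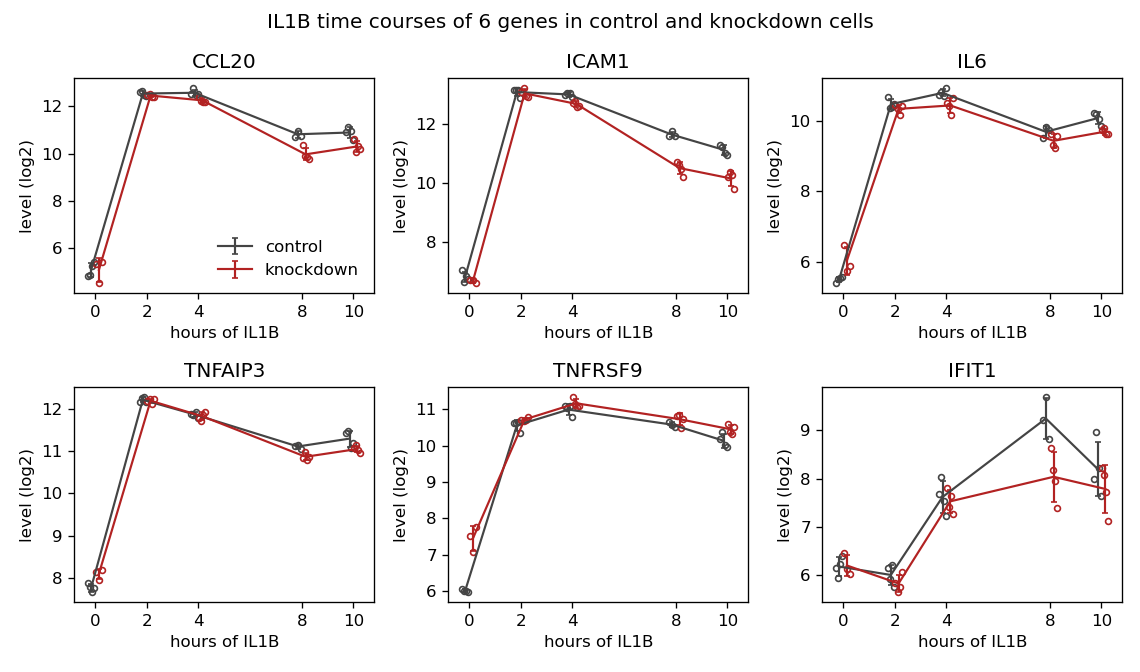
Levels (log2) of CCL20, ICAM1, IL6, TNFAIP3, TNFRSF9 and IFIT1 against hours of IL1B. Open circles are single arrays, lines join group means and bars show the SD, with controls in dark grey and knockdown in red; at 0 h TNFRSF9 stood at 6.00 in controls and 7.44 in knockdown, and at 8 h ICAM1 stood at 11.65 and 10.51.

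Inflammatory gene groups rose together under IL1B in control cells, as the mean of 4 hours. All 20 measured cytokines and chemokines rose (camera adjusted p = 5.71e-37, 1.32e-05 with an estimated correlation), with a median of 2.92 and CCL20 (6.61 ± 0.12) and CCL5 (6.55 ± 0.12) at the top. All 22 NF-kB subunits and feedback regulators rose (1.01e-33, and 5.05e-10 with an estimated correlation), among them the inhibitors TNFAIP3 (3.84 ± 0.06) and NFKBID (2.56 ± 0.06) and the subunit RELB (2.28 ± 0.07). Of 19 adhesion, acute-phase and protease genes 18 rose (1.33e-23, and 1.72e-05 with an estimated correlation), including PI3 (4.14 ± 0.18), the superoxide dismutase SOD2 (3.29 ± 0.05) and LCN2 (3.19 ± 0.18). Of 28 interferon-stimulated genes 26 rose (4.42e-17, and 0.0466 with an estimated correlation), with IRF1 (2.35 ± 0.14), MX1 (2.14 ± 0.17) and SAMD9L (1.87 ± 0.11) among them. Of the 6 genes of MHC class I antigen presentation that were measured, out of 17 in the list, 5 rose (8.64e-04, and 0.0429 with an estimated correlation). They were led by PSMB10 (1.19 ± 0.09) and B2M (0.81 ± 0.08). The counts for these 5 lists were the same adjusted over the list alone. The MHC class I call was lost when probe sets below the median level were left out (adjusted p = 0.054).

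A further 6 lists were called with the preset correlation only. Of 24 DNA replication genes 15 fell and 0 rose, with CDT1 (-0.55 ± 0.11), PRIM1 (-0.54 ± 0.07) and MCM5 (-0.49 ± 0.07) lowest (6.38e-05; adjusted p = 0.138 with an estimated correlation). Of 17 fatty acid and glycerolipid synthesis genes 10 fell, such as ELOVL6 (-0.68 ± 0.09) and ACACA (-0.57 ± 0.06), and ACSL4 rose by 1.23 ± 0.05 (0.0127; adjusted p = 0.0877 with an estimated correlation). Of 25 genes of sphingolipid turnover 14 rose and 5 fell (0.00868, and adjusted p = 0.0877 with an estimated correlation). They included SGPP2 (1.78 ± 0.12), a phosphatase of sphingosine 1-phosphate, SPNS2 (1.39 ± 0.10), its exporter, UGCG (1.36 ± 0.11), which makes glucosylceramide, and SPHK1 (1.28 ± 0.10), a sphingosine kinase. Of 26 genes of the unfolded protein response 10 rose and 1 fell, with DNAJB9 (0.92 ± 0.09) and DNAJC3 (0.77 ± 0.07) highest (0.0192, and adjusted p = 0.293 with an estimated correlation). Of 29 immediate-early and MAP kinase feedback genes 12 rose and 6 fell, with FOS at -1.33 ± 0.13 and FOSL2 at 0.90 ± 0.07 (0.0192, and adjusted p = 0.495 with an estimated correlation). Of 13 prostaglandin and leukotriene genes 5 rose, led by PTGS2 and PLA2G4C (0.91 ± 0.08), and 0 fell (0.037, and adjusted p = 0.293 with an estimated correlation). The prostaglandin call was lost without control 0 h replicate 4 (adjusted p = 0.0695) and with the array score as a covariate (adjusted p = 0.065), and without dim probe sets the calls of sphingolipid turnover, immediate-early and prostaglandin genes were lost (adjusted p = 0.105, 0.117 and 0.117). With the small nucleolar RNA level as a covariate those of immediate-early, prostaglandin and unfolded protein response genes were lost (adjusted p = 0.0726, 0.118 and 0.0607). With the replicate number as a random block those of prostaglandin, fatty acid and unfolded protein response genes were lost (adjusted p = 0.0635, 0.131 and 0.131). Adjusted over the list alone, the counts were the same except for immediate-early genes, with 12 up and 7 down.

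The other 14 lists were not called for IL1B. Among them, 5 of 14 IL1 receptor and proximal signalling genes rose and 2 fell (6 and 2 adjusted over the list alone), with TAB3 at 0.45 ± 0.07. Sphingolipid de novo synthesis had 2 of 10 genes up and 1 down, the ceramide synthase CERS4 (-0.68 ± 0.08), with a median of 0.05 and a test that pointed down. The ATF4 and amino acid response had 8 of 26 up and 8 down, including CHAC1 (1.26 ± 0.10), with a median of -0.01 and a mean of 0.06. Cholesterol synthesis and uptake had 2 of 18 up and 5 down (3 and 5 adjusted over the list alone), with MVK at -0.46 ± 0.07. Glycolysis had 2 of 19 up and 5 down, with the glucose transporter SLC2A3 at -1.10 ± 0.10. Oxidative phosphorylation had 2 of 25 up and 2 down (0 and 1 adjusted over the list alone), and mitosis had 4 of 23 up and 2 down. For p53 targets 3 of 21 rose and 9 fell (5 and 10 adjusted over the list alone), for NRF2 targets 1 of 19 rose and 6 fell, and for calcium stores 5 of 14 rose and 6 fell. Of 15 17q12-q21 neighbours of ORMDL3 2 rose, CSF3 among them, and 4 fell, with a median of -0.04 and a mean of 0.13. Of 9 lung epithelial markers 2 rose, LAMP3 by 2.37 ± 0.07, and 5 fell (2 and 6 adjusted over the list alone), with a median of -0.32 and a mean of 0.01. Of 4 measured leukocyte markers 1 rose, ITGAM (0.61 ± 0.07), and of 2 fibroblast and endothelial markers 1 rose, CDH5 (1.12 ± 0.09). Where no count adjusted over the list alone is given, it was the same.

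The second comparison asked what knockdown changed across the 5 hours. CALB2, a calcium-binding protein, was higher by 0.84 ± 0.10 in knockdown, and KLHL4 (0.75 ± 0.05), ANKRD1 (0.74 ± 0.07), GALNT5 (0.72 ± 0.05), the integrin ITGB4 (0.69 ± 0.07) and the matrix protein SPARC (0.67 ± 0.07) were higher too. ACAT1, a mitochondrial acetyl-CoA acetyltransferase, was lower by -0.88 ± 0.07, with DIPK2A (-0.86 ± 0.04), CARNMT1 (-0.85 ± 0.04), which methylates carnosine, and QNG1 (-0.78 ± 0.07). The stress protein NUPR1 (-0.76 ± 0.05), the sphingosine 1-phosphate phosphatase SGPP1 (-0.75 ± 0.04), the natriuretic peptide receptor NPR3 (-0.72 ± 0.06), the lysosomal phospholipase PLA2G15 (-0.63 ± 0.04) and the chemokine CXCL10 (-0.62 ± 0.08) were also lower. SGPP1 stood at 8.79 ± 0.12 (SD, n = 4) in controls and 7.99 ± 0.15 (SD, n = 3) in knockdown at 0 h, and at 8.79 ± 0.14 and 8.07 ± 0.15 (SD, n = 4 each) at 10 h. The inflammatory genes ICAM1 (-0.53 ± 0.05) and CCL20 (-0.37 ± 0.07) were lower, while CXCL8 (-0.04 ± 0.05), SOD2 (0.00 ± 0.03) and NFKBIA (-0.04 ± 0.03) did not pass the test. The serine palmitoyltransferase subunits SPTLC1 (-0.08 ± 0.04) and SPTLC2 (0.00 ± 0.04) and the stress sensors ATF6 (0.01 ± 0.03) and HSPA5 (0.05 ± 0.03) did not pass it either.

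For the mean of 5 hours 3332 probe sets were called, 1574 up and 1758 down. The changes were small: the median size was 0.17, and 21 probe sets rose and 15 fell by more than 1.5-fold. Of the 3332, 2511 (75.4%) had 1 sign at all 5 hours. Called in 1 direction at each of the 5 hours were 53 probe sets, ORMDL3, ACAT1, DIPK2A, CARNMT1, NUPR1, SGPP1, KLHL4 and GALNT5 among them. The count fell to 2178 when probe sets below the median level were left out.

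Cholesterol synthesis and uptake was the gene group with the smallest p for knockdown. Of its 18 measured genes 12 were higher and 0 lower, by small amounts, with a median of 0.14 (camera adjusted p = 3.12e-07; adjusted p = 0.12 with an estimated correlation). HMGCS1, which forms HMG-CoA, was higher by 0.34 ± 0.06, INSIG1 by 0.26 ± 0.03, TM7SF2 by 0.26 ± 0.04 and MSMO1 by 0.20 ± 0.04. Of 20 cytokines and chemokines 9 were lower, including CXCL10, the IL1B gene (-0.38 ± 0.07) and CCL20, and IL11 was higher by 0.37 ± 0.06 (0.00624, and adjusted p = 0.459 with an estimated correlation). Of 28 interferon-stimulated genes 12 were lower, among them IFIT1 (-0.37 ± 0.11), CMPK2 (-0.31 ± 0.08) and MX2 (-0.29 ± 0.09), and 0 were higher (0.00624, and adjusted p = 0.556 with an estimated correlation). These 2 lists were not lower at every hour. In knockdown minus control the cytokine list mean was 0.07, 0.05, -0.23, -0.29 and -0.27 at 0, 2, 4, 8 and 10 h. The interferon-stimulated list mean was 0.12, 0.03, -0.07, -0.6 and -0.3. Immediate-early and MAP kinase feedback had 6 of 29 up and 1 down, with FOS at 0.25 ± 0.07 and DUSP5 at -0.22 ± 0.05 (0.0388, and adjusted p = 0.556 with an estimated correlation). Glycolysis had 5 of 19 up and 2 down, with SLC2A3 at 0.50 ± 0.06, ALDOC at 0.38 ± 0.06 and ENO2 at 0.23 ± 0.04 (0.0388, and adjusted p = 0.459 with an estimated correlation). NRF2 targets had 4 of 19 down, with the heme oxygenase HMOX1 at -0.58 ± 0.04 and OSGIN1 at -0.27 ± 0.05 (0.0388, and adjusted p = 0.556 with an estimated correlation). Adjusted over the list alone, 10 cytokines, 13 interferon-stimulated genes and 8 immediate-early genes passed in these directions, and the cholesterol, glycolysis and NRF2 counts were the same. Without dim probe sets, the cholesterol list alone was still called, and the cytokine and interferon-stimulated lists had adjusted p of 0.162 and 0.342. The immediate-early call was lost without control 0 h replicate 4, 2 h replicate 4, 4 h replicate 2 or 3, 8 h replicate 1 or 3 or 10 h replicate 4, or without knockdown 0 h replicate 1 or 2, 2 h replicate 1 or 2, 4 h replicate 2, 8 h replicate 1 or 10 h replicate 1 (adjusted p = 0.0515 to 0.0848), and with fry (adjusted p = 0.0582). The glycolysis call was lost without control 0 h replicate 4, 2 h replicate 4, 4 h replicate 2 or 8 h replicate 1 or 3, or without knockdown 0 h replicate 2, 2 h replicate 2, 4 h replicate 2, 8 h replicate 1 or 10 h replicate 1 (adjusted p = 0.05 to 0.0644), and without all arrays numbered 4 (adjusted p = 0.0575). The NRF2 call was lost without control 0 h replicate 2, 2 h replicate 2, 4 h replicate 2, 8 h replicate 2 or 3 or 10 h replicate 2, or without knockdown 2 h replicate 4 or 10 h replicate 1 or 4 (adjusted p = 0.0515 to 0.0673). It was also lost with array weights (adjusted p = 0.0608), quantile normalization (0.0569), array medians subtracted (0.059) and the array score as a covariate (0.0554), and without all arrays numbered 4 (0.127).

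The other 19 lists were not called for knockdown. NF-kB subunits and feedback regulators had 1 of 22 up and 6 down (3 and 8 adjusted over the list alone), with IRAK3 at -0.52 ± 0.08 and N4BP1 at -0.40 ± 0.05. Its adjusted p of 0.0683 became 0.0479, 0.0441 and 0.0458 without control 4 h replicate 1, knockdown 0 h replicate 4 and knockdown 4 h replicate 4, and 0.0343 with the replicate number as a random block. The ATF4 and amino acid response had 2 of 26 up and 8 down (2 and 10 adjusted over the list alone), with NUPR1, CHAC1 (-0.42 ± 0.06) and GDF15 (-0.36 ± 0.04) lowest. Its adjusted p of 0.06 became 0.0472 with the robust variance trend, 0.0409 with the array score as a covariate and 0.0448 to 0.0494 without any of 7 single arrays. With the replicate number as a fixed or a random block it was 0.0497 or 0.0237. In sphingolipid de novo synthesis, the pathway that ORMDL3 restrains, 1 of 10 genes was called, CERS6 at -0.11 ± 0.03. Sphingolipid turnover had 6 of 25 up and 5 down (7 and 8 adjusted over the list alone), with the sphingomyelinase SMPD1 at 0.41 ± 0.04, SPHK1 at 0.40 ± 0.06 and SGPP2 at -0.32 ± 0.07 beside SGPP1. The unfolded protein response had 2 of 26 up and 6 down (3 and 7 adjusted over the list alone), with SEL1L at -0.15 ± 0.04. Adhesion, acute-phase and protease genes had 4 of 19 up and 3 down (5 and 5 adjusted over the list alone), with LCN2 at -0.56 ± 0.10 and MMP9 at 0.44 ± 0.05, and a median of 0 beside a mean of -0.04 under a test that pointed up. Fatty acid and glycerolipid synthesis had 4 of 17 up, with ACSS2 at 0.38 ± 0.04, and p53 targets had 5 of 21 up and 1 down (5 and 2 adjusted over the list alone), with FAS at 0.31 ± 0.03 and TP53INP1 at -0.44 ± 0.04. The p53 list, at 0.0826, was called with the replicate number as a fixed block (0.0497), array weights (0.0435), the array score (0.039) and without all arrays numbered 4 (0.0273), and without knockdown 0 h or 4 h replicate 4 (0.0441 and 0.0448). Calcium stores had 3 of 14 up and 3 down, with the channel TRPC1 at -0.44 ± 0.03. Of 15 17q12-q21 neighbours 0 were higher and 2 lower (1 adjusted over the list alone), with STARD3 at -0.18 ± 0.04. Lung epithelial markers had 3 of 9 up and 1 down, with KRT19 at 0.60 ± 0.04, and were called with the replicate number as a random block (adjusted p = 0.0237). IL1 receptor and proximal signalling had 3 of 14 down, with IL1RAP at -0.17 ± 0.04, and prostaglandin and leukotriene genes had 3 of 13 up and 2 down, with HPGD at 0.35 ± 0.04 and PTGER4 at -0.33 ± 0.05. DNA replication had 2 of 24 up and 4 down, with UHRF1 at 0.22 ± 0.05 and MCM2 at -0.17 ± 0.03, and mitosis had 3 of 23 up (1 adjusted over the list alone). MHC class I antigen presentation had 1 of 6 up (2 adjusted over the list alone), and oxidative phosphorylation had 1 of 25 down (0 adjusted over the list alone). Of 4 leukocyte markers 1 was higher, CD68 by 0.14 ± 0.04 (1 up and 1 down adjusted over the list alone), and of 2 fibroblast and endothelial markers limma called 0. Where no count adjusted over the list alone is given, it was the same.

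Knockdown was also compared with control within each hour. At 0 h, before IL1B, TNFRSF9 was higher by 1.44 ± 0.12, at 7.44 ± 0.36 (SD, n = 3) against 6.00 ± 0.04 (SD, n = 4), and CPA4, a carboxypeptidase, by 1.33 ± 0.20, while QNG1 (-0.96 ± 0.15) and DIPK2A (-0.93 ± 0.09) were lower. At 2 h SEMA7A, a membrane semaphorin, was higher by 0.94 ± 0.16 and ACAT1 (-1.16 ± 0.14) and QNG1 (-1.11 ± 0.14) were lower. At 4 h GALNT5 was higher by 0.83 ± 0.10 and NCR3LG1 (-0.96 ± 0.12), a ligand of a natural killer cell receptor, was lower. At 8 h ITGB4 was higher by 0.97 ± 0.15, and IDO1, an enzyme of tryptophan breakdown (-1.30 ± 0.26), ICAM1 (-1.15 ± 0.12) and CCL20 (-0.85 ± 0.16) were lower. At 10 h TDO2, another enzyme of tryptophan breakdown, was higher by 0.87 ± 0.17, and ICAM1 (-0.98 ± 0.11) and TNFAIP6 (-0.97 ± 0.16) were lower. The interferon-stimulated gene IFIT1 was lower at 8 h by -1.21 ± 0.26 (adjusted p = 0.0083), but the call was lost without control 8 h replicate 2 (-0.99, adjusted p = 0.0735) or knockdown 8 h replicate 4 (-0.99, adjusted p = 0.0545). IL6 at 0 h was 0.53 ± 0.13 (adjusted p = 0.016), which rested on knockdown 0 h replicate 1 (0.31 without it, adjusted p = 0.255).

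At 0, 2, 4, 8 and 10 h, 480, 896, 267, 417 and 330 probe sets were called. At 0 h 337 were up (70.2%), against 57.3% with array medians subtracted and 58.6% with quantile normalization, and with the replicate number as a block the count was 750. At 2 h 451 were up and 445 down, at 4 h 161 and 106, and at 10 h 158 and 172. At 8 h 234 were up (56.1%), against 70.1% with array medians subtracted and 65.1% with quantile normalization. The array score, a measure of differences between arrays of 1 group, averaged 0.88 ± 0.73 (SD, n = 4) in knockdown 2 h and -0.13 ± 1.32 (SD, n = 4) in control 2 h. At 8 h it averaged -0.13 ± 1.06 (SD, n = 4) in knockdown and -0.88 ± 0.56 (SD, n = 3) in controls. The array numbered 4 was highest on the component behind this score in each of the 9 groups that have one, and control 8 h has none. With this score as a covariate, 865, 740, 593, 495 and 665 probe sets were called at the 5 hours, and without the arrays numbered 4, 259, 1653, 253, 323 and 128. Array weights gave 1552 (58.1% up), 2240 and 659 at 0, 2 and 10 h. Single arrays moved these counts by more than 1.5 times. The count at 0 h was 317 and 295 without control replicates 2 and 3 and 274, 306 and 272 without knockdown replicates 1, 2 and 4. At 2 h it was 453, 473, 392 and 1502 without control replicates 1, 2, 3 and 4 and 485 without knockdown replicate 1. At 4 h it was 152 without control replicate 3 or knockdown replicate 4. At 8 h it was 188, 234 and 177 without control replicates 1, 2 and 3 and 170 without knockdown replicate 4. At 10 h it was 155, 134 and 215 without control replicates 1, 3 and 4 and 179 and 135 without knockdown replicates 1 and 4. A fit to only the arrays compared called 92, 291, 36, 46 and 55.

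**Figure D3:**
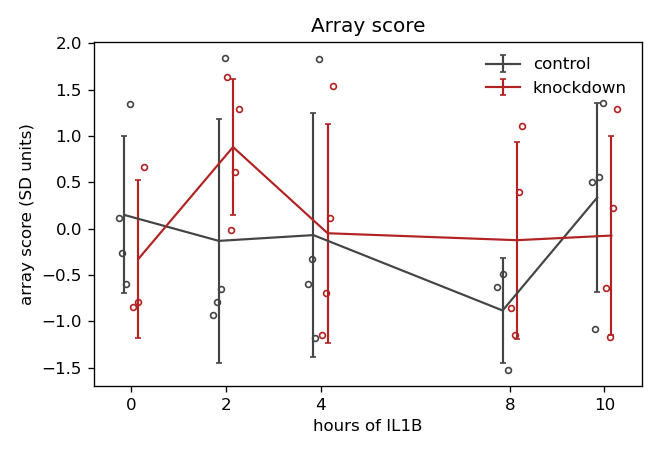
Array score of each of the 38 arrays against hours of IL1B. Open circles are single arrays, lines join group means and bars show the SD, with controls in dark grey and knockdown in red; control 2 h replicate 4 lies at 1.84 and the other control arrays at 2 h lie at -0.93 to -0.65.

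The third comparison asked whether cells with less ORMDL3 responded differently to IL1B. TNFRSF9 rose less in knockdown at every hour, with differences in response of -1.27 ± 0.16, -1.27 ± 0.16, -1.29 ± 0.16 and -1.13 ± 0.16 at 2, 4, 8 and 10 h (joint adjusted p = 5.19e-05). Its level after IL1B was close in both arms, at 10.73 ± 0.05 against 10.56 ± 0.15 (SD, n = 4 each) at 2 h, and its level at 0 h was the one that differed. All 4 differences use the same 0 h arrays, so they are not separate observations. ICAM1 had the reverse form: its levels were 13.06 ± 0.14 in knockdown and 13.10 ± 0.13 in controls at 2 h (SD, n = 4 each). At 8 h they were 10.51 ± 0.22 (SD, n = 4) and 11.65 ± 0.10 (SD, n = 3). The difference in its response was -0.99 ± 0.16 at 8 h (adjusted p = 0.0034) and -0.83 ± 0.16 at 10 h (joint adjusted p = 1.01e-04). EBI3, a subunit of interleukin 27, rose from 7.22 ± 0.07 (SD, n = 3) in knockdown and 6.30 ± 0.11 (SD, n = 4) in controls to 10.10 ± 0.14 and 10.04 ± 0.17 (SD, n = 4 each) at 10 h (joint adjusted p = 0.00191). NFKB2, an NF-kB subunit, had a difference of -0.57 ± 0.10 over the mean of 4 hours (joint adjusted p = 0.00885). Its level was 1.46-fold higher in knockdown at 0 h, and the arms were 1.02-fold to 1.17-fold apart after IL1B, so the 0 h level made most of this difference. The difference for IL6 was -0.82 ± 0.15 over the mean of 4 hours (adjusted p = 0.0067). IL6 was 1.45-fold higher in knockdown at 0 h and 1.09-fold to 1.3-fold lower after IL1B.

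Called for a different response were 4 probe sets at 2 h (1 up and 3 down), 10 at 4 h (1 and 9), 33 at 8 h (2 and 31), 12 at 10 h (0 and 12), 34 for the mean of 4 hours (1 and 33) and 24 in the joint test. With the replicate number as a block, the counts at 2, 4 and 8 h were 7, 30 and 70, and IL6 was called at 8 h (-0.77, adjusted p = 0.0385). For these hours the numbers pair samples with 0 h within each arm. Between the arms they do not, with lowest same-numbered correlations of -0.105, -0.118 and -0.217 at 2, 4 and 8 h. Array weights gave 829 (37.6% up), 46, 240 (30% up) and 46 at 2, 4, 8 and 10 h, 536 for the mean (33.2% up, against 2.94% in the main fit) and 457 jointly. A fit to only the arrays compared gave 2, 0 and 0 at 4, 8 and 10 h. Quantile normalization gave 6, 14 and 18, and array medians subtracted 6, 14 and 17, at 4 h, 8 h and for the mean. With the array score as a covariate the counts were 25 at 4 h, 30 at 10 h and 53 jointly, and with the small nucleolar RNA covariate 17 at 8 h and 16 for the mean. The small nucleolar RNA level itself rose more in controls, from 6.72 ± 0.21 (SD, n = 4) at 0 h to 7.34 ± 0.21 (SD, n = 3) at 8 h. In knockdown it went from 7.04 ± 0.16 (SD, n = 3) to 7.15 ± 0.41 (SD, n = 4). Without the arrays numbered 4 the counts of calls were 27, 5, 20 and 6 by hour and 22 for the mean. Without dim probe sets 17 were called at 4 h, and with averaged probe sets 1 at 2 h. Single arrays moved these counts by more than 1.5 times. The count at 2 h was 10 without control 2 h replicate 4. At 4 h it was 5 without control 0 h replicate 2 or 3, control 4 h replicate 1, 2 or 3, knockdown 0 h replicate 4 or knockdown 4 h replicate 2 or 3, and 6 without knockdown 0 h replicate 1 or knockdown 4 h replicate 1. At 8 h it was 14 and 19 without control 0 h replicates 2 and 3, 19 and 20 without control 8 h replicates 1 and 3, 12 and 19 without knockdown 0 h replicates 1 and 4 and 20 without knockdown 8 h replicate 3. At 10 h it was 5 and 19 without control 0 h replicates 2 and 4, 5 without control 10 h replicate 1, 4 without knockdown 0 h replicate 1 and 7 without knockdown 10 h replicate 4. The count for the mean was 19 without control 0 h replicate 2 and 8 and 14 without knockdown 0 h replicates 1 and 2. The joint test gave 9 and 11 without control 0 h replicates 2 and 3 and 12 without knockdown 0 h replicate 1. It gave 13 without control 2 h replicate 3 or knockdown 8 h replicate 1, and 14 without control 10 h replicate 1, knockdown 2 h replicate 2 or knockdown 8 h replicate 3 or 4. It gave 15 without control 4 h replicate 3, control 8 h replicate 2, knockdown 2 h replicate 1 or knockdown 10 h replicate 1 or 4. For IL6 the mean difference was -0.59 without knockdown 0 h replicate 1 (adjusted p = 0.0871). For ICAM1 at 10 h the call was lost without control 0 h replicate 2 (-0.77), control 10 h replicate 1 (-0.78) or 2 (-0.80), knockdown 0 h replicate 1 (-0.81) or 2 (-0.81) or knockdown 10 h replicate 4 (-0.71), with adjusted p of 0.0509 to 0.0893.

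As groups, NF-kB subunits and feedback regulators rose less in knockdown, with 3 of 22 called down for the mean difference in response and a list median of -0.13 (camera adjusted p = 2.42e-04, and 0.0279 with an estimated correlation). The 3 were TNIP3 (-0.67 ± 0.13), NFKB2 and TNFAIP3 (-0.47 ± 0.09), and adjusted over the list alone 9 were down and 2 up. TNIP3, NFKB2 and TNFAIP3 were 1.32-fold, 1.46-fold and 1.26-fold higher in knockdown at 0 h, which supplies a part of their differences. The list mean in knockdown minus control was 0.04, 0.03, -0.12, -0.15 and -0.18 at 0, 2, 4, 8 and 10 h. Of 20 cytokines and chemokines 2 were down, IL6 and IL32 (-0.74 ± 0.14), or 8 adjusted over the list alone (2.42e-04, and adjusted p = 0.482 with an estimated correlation). IL32 was 1.42-fold higher in knockdown at 0 h. Of 28 interferon-stimulated genes limma called 0, or 6 down adjusted over the list alone, but the list median was -0.38 and the list was called down (5.08e-08, and adjusted p = 0.482 with an estimated correlation). IRF1 (-0.63 ± 0.20), IFIH1 (-0.61 ± 0.17) and HERC5 (-0.60 ± 0.15) had the largest differences of its members. Mitosis genes had a median of -0.11 with 0 of 23 called (0.0465, and adjusted p = 0.532 with an estimated correlation), and this call was lost without control 0 h replicate 2 or 3, 2 h replicate 1 or 4, 4 h replicate 4, 8 h replicate 1 or 3 or 10 h replicate 3, or without knockdown 0 h replicate 1 or 4, 2 h replicate 2 or 3, 4 h replicate 1 or 3, 8 h replicate 4 or 10 h replicate 1 or 4 (adjusted p = 0.05 to 0.23). It was also lost with the replicate number as a fixed block (adjusted p = 0.0533), array weights (0.303), quantile normalization (0.0542), array medians subtracted (0.063), averaged probe sets (0.0544) and fry (0.26), without dim probe sets (0.0872) and without all arrays numbered 4 (0.116). The cytokine call was lost with array weights (adjusted p = 0.0548) and fry (0.0747), and the interferon-stimulated call with fry (0.114). Of the 21 lists not called, 19 had 0 genes called, and the others had 1 each, PLAU (-0.56 ± 0.12) among adhesion, acute-phase and protease genes and ACSL4 (-0.38 ± 0.07) in fatty acid and glycerolipid synthesis. The adhesion, acute-phase and protease list, at an adjusted p of 0.0606, was called with the robust variance trend (0.0427), with the replicate number as a random block (0.0482), without dim probe sets (0.00481) and without any of 8 single arrays (0.0257 to 0.0477). Lung epithelial markers were called without dim probe sets (0.0438), and NRF2 targets with the small nucleolar RNA covariate (0.0293). Adjusted over the list alone, turnover of sphingolipids had 1 up and 3 down, adhesion, acute-phase and protease genes 3 down, the unfolded protein response 2 down and immediate-early genes 1 up and 1 down. Prostaglandin genes, MHC class I genes and leukocyte markers then had 1 down each, and NRF2 targets 1 up. Leaving out knockdown 0 h replicate 1 ended the calls of IL32 (-0.72, adjusted p = 0.063), TNFAIP3 (-0.45, adjusted p = 0.063), PLAU (-0.59, adjusted p = 0.0653) and ACSL4 (-0.33, adjusted p = 0.0871). Leaving out knockdown 0 h replicate 2 ended those of IL32 (-0.69, adjusted p = 0.0633), TNIP3 (-0.58, adjusted p = 0.107) and PLAU (-0.59, adjusted p = 0.0581), and leaving out knockdown 0 h replicate 4 those of TNIP3 (-0.62, adjusted p = 0.0702), TNFAIP3 (-0.42, adjusted p = 0.0512) and PLAU (-0.49, adjusted p = 0.123). The call of PLAU was also lost without control 0 h replicate 2 (-0.53, adjusted p = 0.0868) or 4 (-0.50, adjusted p = 0.0838).

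**Figure D4:**
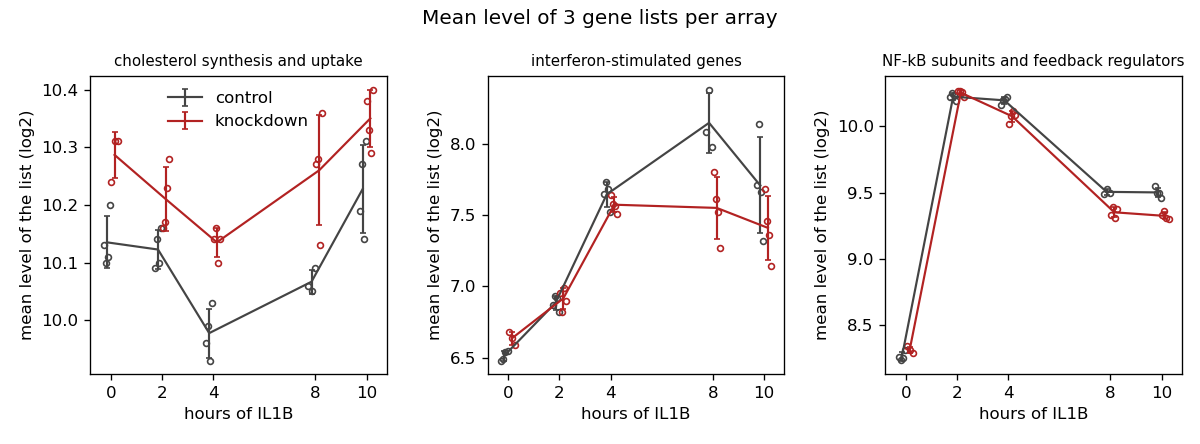
Mean level (log2) of the genes of cholesterol synthesis and uptake (18 genes), the interferon-stimulated genes (28) and the NF-kB subunits and feedback regulators (22) against hours of IL1B. Open circles are single arrays, lines join group means and bars show the SD, with controls in dark grey and knockdown in red; at 8 h the interferon-stimulated mean was 8.15 in controls and 7.55 in knockdown.

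The size of the whole response was compared by the slope of the IL1B changes in knockdown on those in controls, over the probe sets called in controls. The slopes were 0.931 ± 0.048, 0.861 ± 0.034, 0.775 ± 0.033 and 0.806 ± 0.031 (jackknife SE over arrays) at 2, 4, 8 and 10 h. Equal responses simulated with noise drawn independently for each probe set gave 0.94, 0.95, 0.93 and 0.93, since noise in the changes of the arm used for selection lowers the slope. Deviations that the probe sets of an array share are not in this simulation, so its slopes are not a full reference for the measured ones. With the probe sets called in knockdown and the axes exchanged, the slopes were 0.894, 1.054, 1.066 and 1.085, against 0.94, 0.94, 0.92 and 0.92 in that simulation. Among probe sets raised more than 4-fold in the mean of both arms, 55 of 92 had a smaller change under IL1B in knockdown than in controls at 2 h, 92 of 112 at 4 h, 60 of 65 at 8 h and 47 of 56 at 10 h. For the mean of 4 hours 4501 probe sets were called for IL1B in knockdown, 1750 up (38.9%) and 2751 down, against 49.7% up with array medians subtracted, and array weights gave 6825. Genes are not independent replicates in these slopes, and both arms' 0 h arrays enter every one of them.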

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

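The tests of how the array score, whole-array levels, the 0 h arrays and the arrays numbered 4 bear on the 3 patterns weighed here were chosen after the results were seen, apart from the slope test at 2 h, to which the standard errors were added later.

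A single array lay far from the others of its group in 9 of 160 groups tested, and chance alone gives about 1 in 20. ORMDL3 stood at 7.38 in control 2 h replicate 2, with the others at 7.11 to 7.15. ORMDL1 stood at 8.41 in control 10 h replicate 1 (others 8.55 to 8.58) and ORMDL2 at 11.61 in control 4 h replicate 2 (others 11.52 to 11.54). ICAM1 stood at 12.90 in control 2 h replicate 4 (others 13.16 to 13.17), CCL20 at 12.40 in knockdown 4 h replicate 1 (others 12.18 to 12.21), CSF3 at 9.58 in control 10 h replicate 4 (others 10.01 to 10.07) and SPTLC1 at 9.20 in control 2 h replicate 3 (others 8.97 to 9.00). The median of small nucleolar RNAs was 7.22 in knockdown 2 h replicate 2 (others 6.97 to 7.01), and the array score was 1.84 in control 2 h replicate 4 (others -0.93 to -0.65).

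The response to IL1B differed between the arms, by limma's joint test, for TNFRSF9 (adjusted p = 5.19e-05), ICAM1 (0.000101), EBI3 (0.00191), NFKB2 (0.00885), ATP2B4 (0.0121), SLC39A8 (0.0193), MCTP1 (0.0229), TOP1 (0.0241), KLHL21 (0.0241) and DKK1 (0.0275). At single hours the differences that passed and were largest in each direction were those of ATP2B4 (0.67) and TNFRSF9 (-1.27) at 2 h, DKK1 (0.40), TNFRSF9 (-1.27) and IL6 (-0.89) at 4 h, MINDY1 (0.64), EPB41L1 (0.52), TNFRSF9 (-1.29) and TNFAIP6 (-1.19) at 8 h, and TNFRSF9 (-1.13) and IL6 (-0.92) at 10 h. The calls of TNFRSF9 held without any single array and in the alternatives that gave it a value. It has no value of its own in the limma fit to only the arrays compared, which called 0 probe sets at 8 h and 0 at 10 h (1498 and 847 at an unadjusted p under 0.05), so its calls at those hours were lost there. Joint calls were lost for KLHL21 without control 2 h replicate 1, 3 or 4 or knockdown 2 h replicate 2 or 4 (0.0515 to 0.0659), for MCTP1 without control 0 h replicate 2 or 3, control 8 h replicate 3 or knockdown 0 h replicate 1 (0.0552 to 0.09), for TOP1 without control 0 h replicate 2 or 3 or knockdown 0 h replicate 1 or 2 (0.051 to 0.0791) and for DKK1 without control 0 h replicate 2, control 4 h replicate 2 or 3 or knockdown 4 h replicate 1 or 2 (0.0521 to 0.0828). The 2 h call of ATP2B4 was lost without control 0 h replicate 1, 3 or 4, control 2 h replicate 1, 2 or 3, knockdown 0 h replicate 1 or 4 or any knockdown 2 h array (adjusted p = 0.0534 to 0.151). The 4 h call of DKK1 was lost without control 0 h replicate 2 or 3, control 4 h replicate 2 or 3, knockdown 0 h replicate 1 or 4 or knockdown 4 h replicate 1 or 2 (0.0658 to 0.117). The 8 h call of EPB41L1 was lost without control 0 h replicate 2, 3 or 4, control 8 h replicate 1 or 3, knockdown 0 h replicate 1 or 4 or knockdown 8 h replicate 2, 3 or 4 (0.0532 to 0.2), and that of TNFAIP6 without control 0 h replicate 2, control 8 h replicate 2 or knockdown 0 h replicate 1 or 4 (0.0501 to 0.0702). The call of IL6 at 4 h was lost without control 0 h replicate 1, 2 or 3, any control 4 h array, knockdown 0 h replicate 1 or knockdown 4 h replicate 1, 2 or 3 (0.0504 to 0.201), and at 10 h without control 0 h replicate 2, control 10 h replicate 1 or 2, knockdown 0 h replicate 1 or knockdown 10 h replicate 3 or 4 (0.0515 to 0.119). With quantile normalization the calls of IL6 at 4 h (adjusted p = 0.0712), EPB41L1 (0.0521) and TNFAIP6 (0.0521) at 8 h and the joint calls of TOP1 (0.0838) and KLHL21 (0.0578) were lost. With array medians subtracted those of IL6 at 4 h (0.0634), EPB41L1 (0.052) and TOP1 (0.0968) were lost, with array weights that of IL6 at 4 h (0.0653), and with averaged probe sets that of ATP2B4 (0.0594). With the small nucleolar RNA covariate the calls of ATP2B4 (0.0925), IL6 at 4 h (0.0725) and 10 h (0.0514), EPB41L1 (0.182), TNFAIP6 (0.079) and, jointly, MCTP1 (0.0617) were lost. Without the arrays numbered 4 those of ATP2B4 (0.0612), DKK1 (0.171), IL6 at 4 h (0.0903) and 10 h (0.066), EPB41L1 (0.125), TNFAIP6 (0.107) and, jointly, SLC39A8 (0.0989), TOP1 (0.13) and DKK1 (0.0962) were lost. The 8 h call of MINDY1 was lost without control 8 h replicate 1 (0.54, adjusted p = 0.0719) or knockdown 0 h replicate 1 (0.54, adjusted p = 0.0704).

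Other splits of the same arrays were counted for each total. For IL1B in controls at 2, 4, 8 and 10 h, 1 of 35 splits, the real one, gave as many calls, with 2904, 5484, 4969 and 5030 against 235, 1198, 3059 and 829 in the highest other split. For knockdown at 0, 2, 4, 8 and 10 h it was again 1 of 35, with 480, 896, 267, 417 and 330 against 124, 11, 183, 102 and 5. Where numbers pair samples, which holds for IL1B at 2, 4 and 8 h and knockdown at 0 h, 8 splits part every pair, too few for a share under 0.05, and the highest of the others among these was 0, 0 and 2914 for IL1B at 2, 4 and 8 h and 20 for knockdown at 0 h. The split with 2914 kept the 8 h arrays together and joined 1 untreated array to them, replicate 4, which has no partner at 8 h, and the one with 3059 did the same with replicate 1. Of 100 splits each, 1 gave as many calls as the mean contrasts, with 5688 against 2913 for IL1B in controls, 4501 against 1013 for IL1B in knockdown and 3332 against 27 for knockdown. For the difference in response, 4 of 100 splits gave at least 4 calls at 2 h (highest other 474), 3 gave at least 10 at 4 h (19), 2 gave at least 33 at 8 h (89), 3 gave at least 12 at 10 h (288), 3 gave at least 34 for the mean (50) and 2 gave at least 24 in the joint test (384). For IL1B at 10 h and for knockdown at 2, 4, 8 and 10 h the share is under 0.05 if the arrays can be exchanged freely. Some same-numbered arrays deviate together in part of these comparisons as well. If the numbers pair samples there too, only 8 splits part every pair, and chance is not excluded. For the means and the difference in response the shares are under 0.05 too, but these splits took no account of the pairing. The splits with several times the real count at 2 h, at 10 h and in the joint test point to a structure of the samples, which was not identified. The knockdown effect itself may be part of it, since a split that exchanges the arms at 1 hour turns that effect into a difference in response.

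More probe sets were called for knockdown at 2 h (896) than at the other hours. Along the first component of the differences between arrays of 1 group, knockdown 2 h averaged 0.88 and control 2 h -0.13. Across probe sets, which are not independent replicates, the loadings of this component correlated with the knockdown fold changes at r = 0.53 at 2 h, but also at 0.51 at 8 h and 0.31 at 4 h (-0.03 at 0 and 10 h), so the correlation is not particular to 2 h. With the array score as a covariate the count at 2 h was 740, with 634 probe sets shared, below the 865 at 0 h. A difference between arrays may thus account for the excess, but the score lowered the 2 h count less than it raised that at 0 h, which was 480 without it. With the replicate number as a block and with array weights, the count at 2 h stayed above that at 0 h, so the excess is not settled. Without the arrays numbered 4 the 2 h count was 1653, but this removes control 2 h replicate 4 (score 1.84) and widens the gap in score at 2 h. A larger knockdown effect on the genes moved at the other hours stays open too. The slope of the 2 h changes on the mean of the other hours was 0.91 ± 0.15 (jackknife SE over arrays), beside 0.72 ± 0.26, 0.88 ± 0.18, 0.93 ± 0.12 and 0.69 ± 0.23 at 0, 4, 8 and 10 h, each over its own set of genes, and the gap to the highest, at 8 h, was -0.03 ± 0.20.

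The interferon-stimulated genes rose less in knockdown after 8 h of IL1B, with a median difference in response of -0.79 over 28 genes. The median was -0.73 with the array score as a covariate and -0.72 with array medians subtracted, which argues against either as the whole cause. The list mean at 0 h was higher in knockdown by 0.12 (exact permutation p = 0.029, adjusted 0.073), and the knockdown effect at 8 h alone, which uses no 0 h array, had a median of -0.55, so the 0 h arrays supply a part of the difference in response but not the whole. The list mean at 8 h was 7.27 to 7.80 in the knockdown arrays and 7.98 to 8.38 in the controls, a difference of -0.60 (exact permutation p = 0.029, lower in 4 of 4 arrays). This fails the adjustment over 25 such tests (0.073), which the smallest p for groups of this size, 0.029, could hardly pass. With array medians subtracted the difference was -0.56 (exact permutation p = 0.057). At 10 h it was -0.30 (exact permutation p = 0.26), and over 8 and 10 h it was -0.45 (permutation p = 0.009, not adjusted, hours chosen after the values were seen). The groups at 8 h are unbalanced, since the lowest knockdown array is replicate 4, which controls lack at 8 h and which is lowest on this list in both arms at 4 and 10 h, and without the arrays numbered 4 the difference at 8 h was -0.50 (7.52 to 7.80 against 7.98 to 8.38, exact permutation p = 0.1, the smallest that 20 splits can give) and the median difference in response -0.73. With an estimated correlation the list's mean difference had an adjusted p of 0.482, so a spread shared by these genes between arrays stays open. An effect of ORMDL3 on this response remains a hypothesis. Effects of transfection, and of the siRNAs on other transcripts, were not tested and stay open beside it.

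Cholesterol synthesis genes were higher in knockdown over the 5 hours, with a median of 0.14 over 18 genes. The median was 0.15 with array medians subtracted, which argues against differences in the level of whole arrays as the cause. It was 0.14 with the array score as a covariate. That score uses only probe sets with an unadjusted p above 0.2 for the mean knockdown effect, so it could hardly differ between the arms over the 5 hours. The unchanged median therefore does not decide on a difference between arrays along the score. The list mean was higher by 0.16, 0.09, 0.16, 0.19 and 0.12 at 0, 2, 4, 8 and 10 h (exact permutation p = 0.029, 0.029, 0.029, 0.057 and 0.057). This fails the adjustment at each hour (0.073 to 0.089), which the smallest p for groups of this size, 0.029, could hardly pass. The 5-hour mean of 0.14 had a permutation p of 1e-05, the smallest that 100000 resamples can give. That permutation sets whole arrays against each other, which argues against a chance spread shared by these genes between arrays if the arrays are independent, but same-numbered arrays deviate together in part of the comparisons. With an estimated correlation, against other genes, the list had an adjusted p of 0.12. Effects of the siRNAs on other transcripts, and of transfection, were not tested and stay open beside an effect of ORMDL3 itself.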

How the results depend on the processing

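The array score and small nucleolar RNA covariates and the exclusion of arrays numbered 4 were chosen after seeing the data. ORMDL3 stayed between -2.02 and -1.97 without any single array, and it has no value without dim probe sets because it lies below the median level. Of 517 pairs of a named gene and a contrast, 348 were called. No called fold change changed sign under any alternative run, and no other pair gained a call with the opposite sign. Changes of sign without a call were not counted, joint tests have no sign, and many called pairs were chosen for large changes. The calls lost were 29 without arrays numbered 4, 19 with the small nucleolar RNA covariate, 10 with quantile normalization, 7 with array medians subtracted and 1 each with array weights and averaged probe sets. With single arrays left out, 9381 of the comparisons were the same, 344 lost the call and 17 gained it. Signal over background was not given, so how far dim levels limit the smaller calls is open. Unless stated, the cause of a change was not tested.

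With the replicate number as a replicate block, knockdown at 0, 2, 4 and 10 h gave 750, 1770, 623 and 670 calls, and the difference in response gave 7, 30, 70 and 38 at 2, 4, 8 and 10 h, 65 for the mean and 68 jointly. As a random replicate block it gave 1566, 501 and 574 for knockdown at 2, 4 and 10 h and 7, 24, 64, 28, 57 and 50 for the difference in response. The numbers pair samples only in the comparisons named with the methods. There the block moved the count of knockdown at 0 h. For the difference in response at 2, 4 and 8 h the numbers pair samples within each arm but not between the arms at those hours. The block moved these counts too and gave IL6 a call at 8 h (-0.77, adjusted p = 0.0385). It ended no call of a named gene there and moved no other count by more than 1.5 times. The list tests use means over hours that the numbers do not all pair. With the fixed block the ATF4 and p53 lists were called for knockdown (adjusted p = 0.0497 each) and mitosis was not called for the difference in response (0.0533). With the random block NF-kB (0.0343), ATF4 and lung epithelial (0.0237 each) lists were called for knockdown and adhesion, acute-phase and protease genes for the difference in response (0.0482), while for IL1B prostaglandin (0.0635), fatty acid and unfolded protein response genes (0.131 each) were not. As a hint from the data, 28 of 38 arrays correlated best with their own number.

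Array weights gave 6825 for IL1B in knockdown, 1552, 2240 and 659 for knockdown at 0, 2 and 10 h, 829, 46, 240 and 46 for the difference in response at 2, 4, 8 and 10 h, 536 for its mean, 457 jointly and 2 lists for its mean. Without dim probe sets, where fewer were tested, IL1B in controls gave 1792, 3242, 3026 and 2966 and 3304 for the mean, IL1B in knockdown 2651, the knockdown mean 2178, the difference in response at 4 h 17, and 7 and 1 lists were called for IL1B and knockdown. Quantile normalization gave 6, 14 and 18, and array medians subtracted 6, 14 and 17, for the difference in response at 4 h, 8 h and the mean. Averaged probe sets gave 1 at 2 h. With the axes exchanged the response slopes at 4, 8 and 10 h were 1.054, 1.066 and 1.085, as selection then lies in the other arm. A fit to only the arrays compared, with fewer samples, gave 92, 291, 36, 46 and 55 for knockdown and 2, 0 and 0 for the difference in response at 4, 8 and 10 h, where limma had 1498 and 847 at an unadjusted p under 0.05 at 8 and 10 h. List calls for IL1B, knockdown and the difference in response numbered 5, 0 and 1 with an estimated correlation (8, 1 and 1 at an unadjusted p under 0.05), against 11, 6 and 4 with the preset one, and 17, 14 and 1 with fry, which compares no list with other genes.

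With the array score as a covariate, knockdown at 0, 4 and 10 h gave 865, 593 and 665, and the difference in response gave 25 at 4 h, 30 at 10 h and 53 jointly. With the small nucleolar RNA covariate it gave 17 at 8 h and 16 for the mean, and the slope at 8 h was 0.81. Without arrays numbered 4, where fewer samples enter, knockdown at 0, 2 and 10 h gave 259, 1653 and 128, and the difference in response gave 27, 5, 20 and 6 at 2, 4, 8 and 10 h and 22 for the mean.

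With each array left out in turn, where fewer samples enter, knockdown at 0, 2, 4, 8 and 10 h gave 272 to 419, 392 to 1502, 152 to 366, 170 to 342 and 134 to 361 calls. The difference in response gave 3 to 10, 5 to 12, 12 to 44, 4 to 19, 8 to 43 for the mean and 9 to 26 jointly, and 3 to 9 lists were called for knockdown. The counts for IL1B stayed within 1.5 times, at 2463 to 2822, 4943 to 5296, 4102 to 4662 and 4423 to 4877 by hour, 4908 to 5765 for the mean and 3209 to 4538 in knockdown, as did the knockdown mean, at 2905 to 3615. The variance trend with robust moderation moved no count by more than 1.5 times.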

Other observations

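The tests of the genes raised most by IL1B, in the last paragraph here, were chosen after the results were seen.

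Genes called for knockdown at 1 hour overlapped with those of other hours, which share no arrays. Between 0 and 2 h, 133 probe sets were up at both and 59 down at both, where independent lists would share 10.5 and 4.4. Between 8 and 10 h, 74 were up and 61 down, against 2.6 and 2.2. These values for independent lists may be too low. All hours share 1 estimate of the spread per probe set, and same-numbered arrays of different hours deviate together in part. Chosen after their values were seen among the 53 probe sets called at all 5 hours were the integrins ITGA2 (0.53 ± 0.03) and ITGAX (0.42 ± 0.04), the ecto-enzyme NT5E (0.49 ± 0.04), the desmosomal cadherin DSC2 (0.51 ± 0.04), the collagen chain COL5A1 (0.50 ± 0.05) and the chromatin protein HMGA2 (0.61 ± 0.05), which were higher in knockdown. Lower at all 5 hours were the secretory pathway genes SEC23A (-0.42 ± 0.03), a subunit of the COPII coat, and SSR1 (-0.56 ± 0.03), a subunit of the translocon-associated complex, as well as HMOX1 (-0.58 ± 0.04) and TRPC1 (-0.44 ± 0.03).

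A hypothesis drawn from these data is that knockdown raises strongly induced genes before IL1B and lowers them late in the response. It was put in numbers on the 52 probe sets raised more than 4-fold by IL1B in the mean of both arms, from the same arrays that prompted it, so the values describe the pattern and are no independent test of it. At 0 h the mean of these genes was higher in knockdown by 0.12 (6.47 to 6.54 in 3 arrays against 6.34 to 6.41 in 4, exact permutation p = 0.029, adjusted 0.073), by a test that ignores the pairing at 0 h. There were 9 called up and 0 down, but only 29 of the 52 were higher, TNFRSF9 by 1.44, and the median change of 0.07 was 0.01 with the array score as a covariate. The mean was lower by -0.30 at 8 h (exact permutation p = 0.057, adjusted 0.089) and by -0.22 at 10 h (exact permutation p = 0.086, adjusted 0.13), and by -0.26 over both hours (permutation p = 0.003, not adjusted), with 10 of the 52 higher at each of these hours, 11 and 10 called down and 0 up by limma, and the medians of -0.25 and -0.21 were -0.22 and -0.25 with the array score. Neither the early nor the late part passes the adjustment at a single hour, which groups of this size could hardly pass, and the hypothesis stays open. For these genes too, effects of transfection and of the siRNAs on other transcripts were not tested.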
